A study of Mus musculus with 8 samples.

How the data were processed

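The series compared sorted leukaemic bone marrow cells of 4 mice that carried an shRNA against Fubp1 with those of 4 mice that carried a scrambled shRNA. Per the series' design text, donor marrow from mice given 5-fluorouracil was transduced with a retrovirus carrying BCR-ABL1 and a red fluorescent protein, and with a lentivirus carrying the shRNA and the Venus fluorescent protein. The cells were then transplanted into recipients irradiated with 900 cGy, which developed a disease like chronic myeloid leukaemia. Per the labels' protocols, live marrow cells positive for both fluorescent proteins and negative for lineage markers were sorted into TRIzol, and 500 ng of RNA per library entered a stranded total RNA kit with ribosomal RNA depletion. The labels name 2 depletion kits and do not say which library was made with which. The sequence of the shRNA is not given in the sources used here.

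The deposited table holds whole-number read counts per gene that the authors made from their sequencing reads, with no normalization, and 1 column per library. Per the submitters' processing notes, CASAVA 1.8 was used. The aligner, the counting program and its strand setting, the gene annotation and the genome build are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads shared by near-identical genes may have been split or dropped by the authors' counting. The same table gives the authors' log2 fold changes with their standard errors, and the authors' p-values with adjusted p-values. Per the submitters' processing notes these come from DESeq2 1.18.1, and per the series' design text from R 3.4.3, with gene names from biomaRt 2.34.2. The authors' own filter, per the design text, was an adjusted p under 0.05 with a log2 fold change above 1 or below -1. The deposited log2 fold changes of genes with few counts lie close to 0, and those of some abundant genes with much spread are smaller than here. They were therefore treated as moderated estimates and kept apart from the fold changes computed here.

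Columns were matched to samples by the number that the column name shares with the sample's description, and 0 columns of per-sample values were left unmatched. Groups and replicate numbers come from the sample titles. Each library is 1 mouse, so the spread between libraries includes the spread between mice. The table held 47729 genes, of which 21471 had no counts in any library and 285 had no gene symbol. Total counts per library ran from 22465303 to 44761356. The 10 most abundant genes took 3.57 to 4.28% of them. A chi-square comparison of each pair of libraries within a group gave 11.8 to 99.1 per degree of freedom, so no library was a copy of another.

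The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 13462. Libraries were scaled by TMM factors, which ran from 0.965 to 1.03. A quasi-likelihood fit with robust dispersion and the group as the only term was followed by the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every log2 fold change is knockdown minus scrambled. Expression is given as CPM, counts scaled by library size and TMM factor, as mean ± SD over 4 libraries per group. In counts simulated from these libraries' means and sizes, 200 of the 13462 tested genes were changed, and 13643 simulated genes passed the filter. There this test called 30 of 67 genes changed 1.5-fold, 41 of 67 changed 2-fold and 58 of 66 changed 4-fold, with 9 false calls. On the same simulated libraries limma-voom made 8 false calls. DESeq2 was run there, as on the data, without filterByExpr, on 25132 genes; it made 55 false calls, 27.2% of its calls, which are not counted over the same genes.

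There were 31 gene lists, with 21 genes in more than 1 list. They cover the FUBP family, pathways of leukaemic and progenitor cells, markers of other marrow cells that a sort could let through, and signs of RNA handling. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 30 lists tested. Camera asks whether a list moved relative to the other genes. It was run again with the correlation estimated from the data. Fry was run beside it; its main p tests whether a list's genes move one way on balance, its mixed p tests for changes in either direction, and neither compares the list with other genes. In simulated libraries with no list changed, camera called 0 lists. Genes were drawn there independently of each other, so this does not show how often camera errs on lists of correlated genes. A list's level in a library is the mean log2 CPM of its tested members, centred gene by gene. These levels were compared by exact two-sided permutation over the 70 labelled splits of the 8 libraries, for which the smallest possible p is 0.0286, and adjusted over the lists.

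The genes named in the text follow a rule. It takes Fubp1, Fubp3 and Khsrp always. In each direction it takes the 10 called genes with the largest fold change and the 5 with the smallest p, among genes with a mean of at least 5 CPM, no overlap of the 2 groups, and a symbol that is not a predicted gene, a clone name or an antigen receptor segment. From each list it takes up to 4 called members with the smallest p, or, where none was called, the 2 most abundant members as values only. Other genes are named only where the text says that they were chosen after their values were seen, or as called members of a list. Some genes that the rule takes are not reported here. The groups, the tests of genes and lists, the lists, this rule and all alternatives other than the 2 covariate fits were fixed before the data were examined. Several of the later tests of explanations were chosen after, as stated where they are given.

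The alternatives were DESeq2 1.42.0 and limma-voom with quality weights in place of edgeR; RLE factors, upper quartile factors and library totals in place of TMM; no low count filter and a filter of at least 1 CPM in at least 4 libraries; the replicate number as a block; each of the 8 libraries left out in turn; removal of marker genes of other cells, haemoglobin genes and receptor segments; the estimated correlation and fry for lists; and glmTreat against a fold change of 1.2. After seeing the data, 2 fits were added, with the level of the early granulocyte list or of the immediate early list as a covariate.

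Gene coordinates are those of GENCODE vM21 on the GRCm38 mouse assembly, matched by gene ID. The authors' build is not given in the sources used here, and 47224 of the 47729 IDs (98.9%) and 13421 of the 13462 tested ones were found in that annotation. For a scan of short words in 3′ UTRs, each gene's 3′ UTR of at least 50 bases was taken from the same annotation, and the edgeR statistic of each gene, as a rank-normal score, was regressed on the presence of each 7-base word with 3′ UTR length and GC content in the fit. Words found in at least 100 genes were scored. The scan ran in Python 3.11.15 with numpy 2.4.6.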

Results

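RNA of sorted leukaemic bone marrow cells was sequenced in 8 libraries, 4 from mice with a scrambled shRNA and 4 from mice with an shRNA against Fubp1. The disease model was induced by BCR-ABL1, the fusion kinase of chronic myeloid leukaemia. FUBP1 is a single-strand nucleic acid binding protein known as a regulator of Myc transcription. The sorted cells lacked lineage markers and carried both the BCR-ABL1 and the shRNA reporter. The scrambled libraries held 37095964, 32997556, 38495006 and 22465303 counts, and the knockdown libraries 24042761, 29507760, 32685374 and 44761356. The first principal component of the 13462 tested genes held 61.1% of the variance and the second 13.7%. On the first, knockdown replicate 3 lay among the scrambled libraries, at -29.0, while the other 3 knockdown libraries lay between 34.1 and 81.2 and the scrambled libraries between -57.3 and -13.7. The second separated it, at 42.5.

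The targeted gene was lower in the knockdown libraries by a modest amount. Fubp1 (ENSMUSG00000028034, chromosome 3 from 152210422 to 152236826 on the plus strand, GRCm38) measured 296, 284, 291 and 396 CPM in scrambled replicates 1 to 4, and 281, 228, 220 and 239 CPM in knockdown replicates 1 to 4. Its knockdown level was 76.5% of the scrambled level, a log2 fold change of -0.39 (SE 0.12). Over the alternatives that value ran from -0.46 without knockdown replicate 1 to -0.25 with limma-voom. It was -0.28 without scrambled replicate 4, the highest library. All 4 knockdown libraries lay below all 4 scrambled ones, with an exact two-sided permutation p of 0.0286, the smallest that this design allows. By edgeR's quasi-likelihood test the gene missed the threshold over all genes, with an adjusted p of 0.0604. Over the alternatives the adjusted p ran from 0.0145 to 0.174; it passed with DESeq2 (0.0145) and with no low count filter (0.0365). No library went against its label, although knockdown replicate 1 was within 4 CPM of the lowest scrambled library.

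Of its paralogs, Khsrp, a KH-domain protein that binds AU-rich RNA, fell by 0.21 on the log2 scale (SE 0.05, adjusted p = 0.0329), from 560 ± 6.23 to 483 ± 29.6 CPM (SD, n = 4 per group). Fubp3 measured 84.1 ± 4.41 and 76.5 ± 4.97 CPM (adjusted p = 0.189). Of the 3 family members, 1 fell over all genes and 2 when adjusted over the list alone, Fubp1 included. Since the list holds the targeted gene, a fall is in part built in, and the paralogs were not tested as a list without it. Camera called this list lower (adjusted p = 0.0432; adjusted p = 0.590 with an estimated correlation). That call ended without scrambled replicate 4 (adjusted p = 0.0660), knockdown replicate 2 (0.0530) or knockdown replicate 4 (0.0673), and with limma-voom or the filter at 1 CPM. It also ended with the early granulocyte (0.120) or the immediate early level (0.0719) as a covariate, 2 fits added after seeing the data; the range over alternatives was 0.00465 to 0.120. Khsrp kept its own call in 2 of the 8 fits that left out a library, with an adjusted p of up to 0.0836.

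Against this modest change of the target, 2062 genes differed between the groups. Of these, 1080 were higher and 982 lower in the knockdown. Changes of over 1 log2 unit were mostly increases, with 581 genes higher and 111 lower. In 1804 of the 2062 genes the 4 knockdown libraries did not overlap the 4 scrambled ones; among all tested genes 2785 did not, where chance gives 2.86% of genes. At an unadjusted p under 0.05 there were 4508 genes. Leaving out a library leaves fewer to test, which can lower the number called whichever mouse it was. The number called also differed with the mouse left out. It was 748, 526 and 657 without scrambled replicates 1, 2 and 3, and 967, 989 and 1373 without knockdown replicates 1, 2 and 4. It was 3425 without knockdown replicate 3. Without scrambled replicate 4 it was 1859, with fewer genes higher (791) than lower (1068). Genes over 1 log2 unit, 692 in all libraries, numbered 272, 220 and 259 without scrambled replicates 1 to 3, 387, 376 and 438 without knockdown replicates 1, 2 and 4, and 1495 without knockdown replicate 3. By the authors' deposited table, 3411 genes passed an adjusted p of 0.05 and 788 of them by over 1 log2 unit. The authors' fold changes were treated as moderated, so the 788 and the 692 are not counted on the same scale. The calls made here that the authors' deposited table also calls in the same direction numbered 2042, with 0 in the opposite direction and 20 called here only.

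Among called genes with a mean of at least 5 CPM and no overlap of the groups, the largest fold change was that of B4galnt4, which encodes a glycosyltransferase. It rose from 1.17 ± 0.0730 to 20.7 ± 2.30 CPM (SD, n = 4 per group), a log2 fold change of 4.14 (SE 0.13, adjusted p = 2.54e-06). The other genes with the smallest p among those that rose were the amino acid transporter genes Slc36a4 (log2 fold change 2.17, SE 0.17) and Slc7a6 (1.25, SE 0.12), Map7d1 (0.75, SE 0.07) and Tcp11l1 (2.04, SE 0.19), with adjusted p of 0.000830, 0.00172, 0.00161 and 0.00192. Large increases also came from Pimreg (3.17), the NF-kB subunit gene Rel (3.12), the tropomyosin gene Tpm4 (3.10) and Dtx4 (2.95), each called with every library left out in turn. In knockdown replicates 1 to 4 Tpm4 measured 8.46, 5.98, 4.38 and 17.8 CPM, and Dtx4 16.7, 10.2, 7.17 and 31.4 CPM. The early granulocyte level, given below, ranked these libraries in the same order, while Pimreg and Rel did not follow it. The 5 other genes with the largest increases had more spread between mice. Tnfrsf13c, the BAFF receptor gene, rose by 3.50 (SE 0.86), from 7.39 ± 7.59 to 81.3 ± 57.4 CPM. Ahnak rose by 3.31, the transcription factor gene Bhlhe40 by 2.87, Atp8b2 by 2.84 and Il6st, which encodes the shared receptor chain of the interleukin-6 family, by 2.71. The authors' deposited log2 fold changes of these 5 genes were smaller, at 1.16, 1.70, 1.54, 1.53 and 1.34 in that order. All 5 lost the call without scrambled replicates 1, 2 or 3, Tnfrsf13c also without knockdown replicate 2, and Il6st also without scrambled replicate 4 and knockdown replicates 1 and 4, with adjusted p of up to 0.0953.

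Among the genes that fell, those with the smallest p moved by about 1 log2 unit in every knockdown mouse. Lmo2, a transcriptional adaptor of haematopoietic progenitors (chromosome 2 from 103957986 to 103981878 on the plus strand), fell from 441 ± 22.1 to 221 ± 7.81 CPM (log2 fold change -1.00, SE 0.05, adjusted p = 0.000119). Rcbtb1 fell from 69.5 ± 4.89 to 31.4 ± 0.817 CPM, Extl3 from 119 ± 5.32 to 61.6 ± 4.48, Nxpe4 from 76.1 ± 1.45 to 36.0 ± 4.24 and Klhl23 from 167 ± 14.8 to 79.0 ± 7.03 CPM (SD, n = 4 per group). These 5 kept their call with each library left out, with an adjusted p of at most 0.00645. Within the same limits the largest decreases were those of the phosphatase gene Ptpn13 (log2 fold change -3.16, SE 0.46) and of Tcf23 (-2.72, SE 0.64). Oxtr fell by 2.03, Trim2 by 2.03, Ugt8a by 1.90, the muscarinic receptor gene Chrm4 by 1.84, Fam198b by 1.78 and Gpx3, an extracellular glutathione peroxidase, by 1.51, and Vsig10 fell from 9.28 ± 1.65 to 2.67 ± 0.437 CPM. Sphk1, which makes sphingosine 1-phosphate, was the most abundant of them and fell from 426 ± 82.8 to 147 ± 39.2 CPM (adjusted p = 0.00692). Tcf23, Trim2, Ugt8a, Fam198b and Gpx3 lost the call without 3 to 6 of the 8 libraries in turn, scrambled replicate 1 in each case, with an adjusted p of up to 0.0854.

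**Figure D1:**
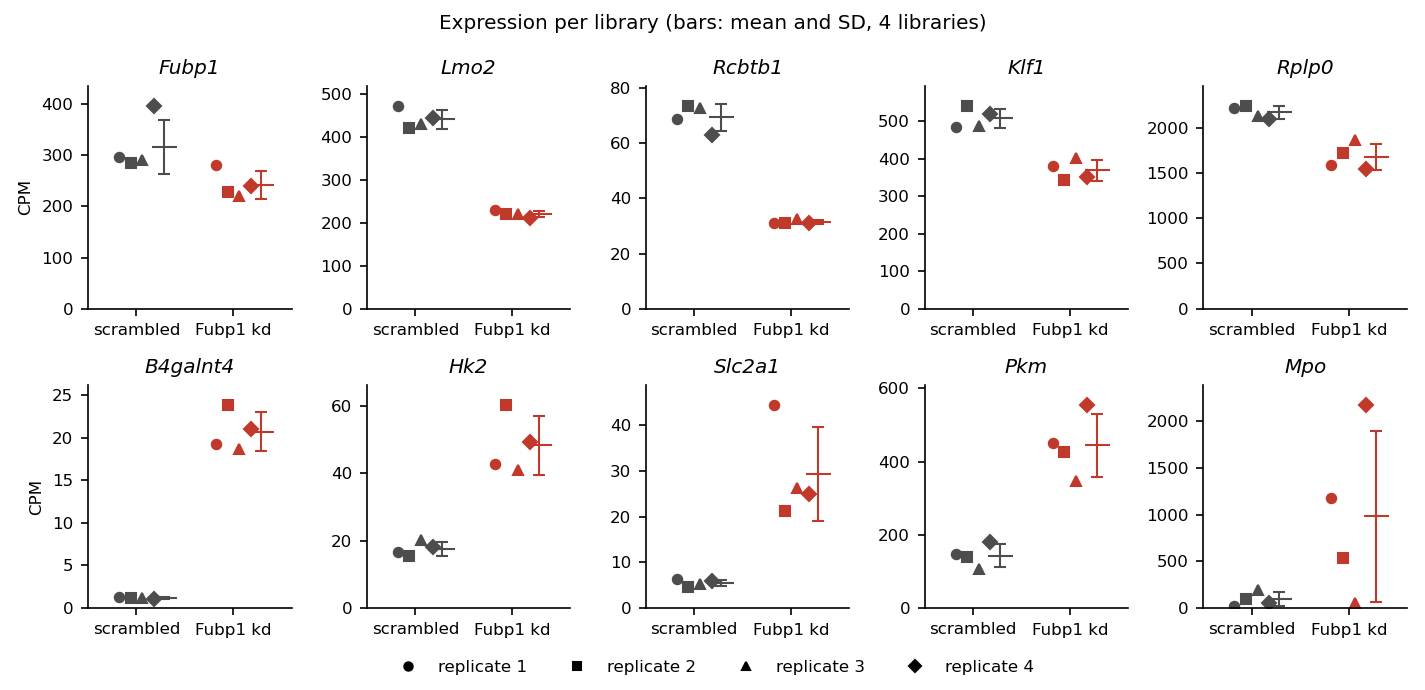
CPM of 10 genes in each of the 4 scrambled and 4 Fubp1 knockdown (kd) libraries, 1 symbol per replicate, with the mean and SD beside them. Lmo2 lies at 221 ± 7.81 CPM in the knockdown against 441 ± 22.1, while Mpo, chosen after its values were seen, lies at 53.4 CPM in knockdown replicate 3 and between 530 and 2169 CPM in the other 3.

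Genes of glycolysis and of the hypoxia response rose in the knockdown. Of the 20 tested members 11 rose and 0 fell, and 13 rose and 2 fell when adjusted over the list alone, with a median log2 fold change of 0.54. The glucose transporter gene Slc2a1 rose from 5.46 ± 0.736 to 29.2 ± 10.3 CPM, the hexokinase gene Hk2 from 17.5 ± 2.07 to 48.3 ± 8.69, and the pyruvate kinase gene Pkm from 143 ± 30.3 to 444 ± 85.2 (SD, n = 4 per group; adjusted p = 0.00192, 0.00192 and 0.00308). Gpi1 (log2 fold change 0.42), Pfkp, Aldoa, Pgk1 and Eno1 of the glycolytic chain and Vegfa, Egln3 and Car9, which respond to hypoxia, also rose. Camera called the list higher (adjusted p = 8.53e-06; adjusted p = 0.590 with an estimated correlation). Its level was above all scrambled libraries in all 4 knockdown libraries (exact permutation p = 0.0286, adjusted p = 0.143). Slc2a1, Hk2 and Pkm kept their calls with each library left out, and Gpi1 lost it without scrambled replicate 2 (adjusted p = 0.0504, with at most that value without any other library). Against 11 members that rose with all libraries, 4 rose without scrambled replicate 2, 6 without scrambled replicate 3 or knockdown replicate 2, 7 without knockdown replicate 4, and 6 with the early granulocyte covariate.

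Ribosomal protein genes were lower by a small amount. Of the 81 tested members 16 fell and 0 rose, and 25 fell when adjusted over the list alone. The fitted change was below 0 in 77 of the 81, with a median of -0.18. Rplp0 fell from 2166 ± 67.8 to 1677 ± 144 CPM and Rpl13a from 1428 ± 103 to 1089 ± 83.8 (SD, n = 4 per group; adjusted p = 0.0122 and 0.0141). Rps27l fell by 0.26 and Rpl15 by 0.25 on the log2 scale. Many of these genes have processed pseudogenes, so their counts are uncertain where the authors' counting could split reads. The number that fell was 3, 1 and 3 without scrambled replicates 1 to 3, 3, 5 and 5 without knockdown replicates 1, 2 and 4, and 34 without knockdown replicate 3. The median was -0.09 with the early granulocyte covariate, and edgeR then called 0 members, with 14 lower at an unadjusted p under 0.05 (adjusted p = 0.00115 by camera). Without a covariate DESeq2 called 25 lower and limma-voom 45. Camera called the list lower (adjusted p = 5.56e-10; adjusted p = 0.590 with an estimated correlation). Rplp0 kept its call with each library left out; Rpl13a lost it without scrambled replicate 2 (adjusted p = 0.0550), Rps27l without scrambled replicate 1 or 2, and Rpl15 without scrambled replicates 2 or 3 or knockdown replicate 1, with an adjusted p of up to 0.0613.

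Some signalling and stress genes also moved. Among targets of STAT5, a transcription factor activated by BCR-ABL1, 2 of 11 tested members rose and 0 fell, and 6 rose when adjusted over the list alone. They were Socs3 (6.47 ± 0.734 to 17.1 ± 2.96 CPM, adjusted p = 0.00274) and the kinase gene Pim1 (121 ± 35.3 to 244 ± 49.1 CPM, adjusted p = 0.0274; SD, n = 4 per group). By camera this list was higher (adjusted p = 0.00184; adjusted p = 0.590 with an estimated correlation). In the NF-kB and cytokine list 2 of 14 rose, Icam1 (log2 fold change 1.78) and the chemokine gene Cxcl2 (2.37), and 7 when adjusted over the list alone. Camera called it higher (adjusted p = 0.00160; adjusted p = 0.590 with an estimated correlation). In the unfolded protein and ATF4 list 6 of 19 rose and 0 fell, and 7 rose and 1 fell when adjusted over the list alone. They were the cystine transporter gene Slc7a11 (1.59), Herpud1 (0.88), the chaperone genes Hspa5 (0.39), Dnajb9 (0.45) and Sdf2l1 (0.79), and Xbp1 (0.78). Camera called this list higher (adjusted p = 0.00452; adjusted p = 0.590 with an estimated correlation). Socs3, Icam1, Slc7a11 and Herpud1 kept their calls with each library left out. Of the unfolded protein list 2 rose without any 1 of the 4 scrambled libraries and 3 without knockdown replicate 2; of the NF-kB list 7 rose without knockdown replicate 3. Pim1 lost it without scrambled replicates 2 or 3 or knockdown replicate 2, Hspa5 without each of the 4 scrambled libraries in turn, and Cxcl2, Dnajb9 and Xbp1 without 6 or 7 of the 8 libraries in turn, with adjusted p of up to 0.0945.

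In the cholesterol synthesis list 5 of 18 tested members rose over all genes and 11 when adjusted over the list alone, with 0 that fell. The fitted change was above 0 in all 18. Among those that rose were the synthase gene Hmgcs1 (25.7 ± 2.72 to 52.3 ± 15.5 CPM), Mvd (12.5 ± 1.85 to 23.6 ± 7.79; SD, n = 4 per group) and Mvk (log2 fold change 0.91). By camera the list was called higher (adjusted p = 3.49e-05; adjusted p = 0.677 with an estimated correlation), and by fry it was not (0.142). The number that rose was 3, 0, 1 and 3 without scrambled replicates 1 to 4, 9 and 3 without knockdown replicates 1 and 2, and 14 with the early granulocyte covariate. The median log2 fold change, 0.67, was 0.42 without knockdown replicate 3 and 1.09 with that covariate. Where edgeR called 0, 9 members were higher at an unadjusted p under 0.05; with all libraries DESeq2 called 11 and limma-voom 7. The level in knockdown replicate 1, -0.16, lay among the scrambled libraries, at -0.47 to -0.11. Mvk lost its call without scrambled replicate 2, Hmgcs1 without scrambled replicate 2 or 3, and Mvd without 6 of the 8 libraries in turn, with adjusted p of up to 0.0969.

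Lineage genes did not move as 1 block. The cells were rich in erythroid transcripts in both groups: Car2, carbonic anhydrase 2, measured 3458 ± 492 CPM in the scrambled and 2112 ± 404 in the knockdown libraries, and Ermap 1511 ± 100 and 985 ± 100 (SD, n = 4 per group). Of the 21 tested erythroid genes 5 fell and 4 rose, and 5 fell and 6 rose when adjusted over the list alone. Those that fell were Car2, Ermap, the transcription factor genes Klf1 (log2 fold change -0.46, adjusted p = 0.00602) and Gata1 (-0.34), and the erythropoietin receptor gene Epor (-0.42). Those that rose were the globin genes Hbb-bs (1.63) and Hbb-bt (1.17), the haem synthesis gene Alas2 (1.40) and Tmod1 (1.41). The globin copies are near-identical, so their split is uncertain. The number that rose was 1 without scrambled replicate 1 or knockdown replicate 1, 7 without knockdown replicate 2, and 0 by edgeR without scrambled replicate 2 or 3, where 5 were higher at an unadjusted p under 0.05. The number that fell was 3 without scrambled replicates 1, 2 or 3 or knockdown replicates 1 or 2. With all libraries DESeq2 called 6 higher and 5 lower, and limma-voom 6 and 6. Camera did not call the list (adjusted p = 0.715), with a median below 0, a mean above it and a test pointing down, or up without scrambled replicate 4 or knockdown replicate 2. Of 10 tested megakaryocyte genes 2 rose, the platelet integrin gene Itga2b (41.0 ± 5.51 to 127 ± 30.1 CPM) and Gp1ba (10.3 ± 1.41 to 16.4 ± 2.65), and 4 when adjusted over the list alone. Without scrambled replicate 4, where 11 were tested, 4 rose, and DESeq2 and limma-voom called 4 each with all libraries. Camera called that list higher (adjusted p = 0.00685; adjusted p = 0.590 with an estimated correlation). Itga2b, Klf1, Ermap and Epor kept their calls with each library left out, while Car2 and Gp1ba lost it without scrambled replicates 1, 2 or 3 or knockdown replicates 1 or 2, with an adjusted p of up to 0.0730.

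Myeloid genes were high in 3 of the 4 knockdown libraries and not in replicate 3. Of the 14 tested genes of early granulocytes 1 rose over all genes, the protease inhibitor gene Cst7 (5.78 ± 1.67 to 24.5 ± 14.7 CPM; SD, n = 4 per group, adjusted p = 0.0344), and 14 when adjusted over the list alone. Over all genes 14 rose without knockdown replicate 3 and 14 with the immediate early covariate; edgeR called 0 without any of the other 7 libraries, with 11 to 14 at an unadjusted p under 0.05. DESeq2 called 15 of 15 and limma-voom 8. The list's level was 2.05, 1.42 and 3.19 in knockdown replicates 1, 2 and 4, and -1.59 in replicate 3, against -2.52 to 0.04 in the scrambled libraries (exact permutation p = 0.0857, adjusted p = 0.214). Camera called the list higher (adjusted p = 0.000147; adjusted p = 0.677 with an estimated correlation). Mpo, the neutrophil myeloperoxidase gene, chosen after its values were seen, ran from 21.1 to 196 CPM in the scrambled libraries and measured 1182, 530, 53.4 and 2169 CPM in knockdown replicates 1 to 4. Of 16 tested monocyte and macrophage genes Klf4 rose (log2 fold change 1.74) and the iron exporter gene Slc40a1 fell by 0.62, and 10 rose and 1 fell when adjusted over the list alone. Without knockdown replicate 3, where 18 were tested, 8 rose, and 9 with the immediate early covariate; edgeR called 1 higher without scrambled replicate 4 and 0 without any of the other 6 libraries, with 6 to 12 at an unadjusted p under 0.05. DESeq2 called 11 of 17 higher and limma-voom 4. Camera called that list higher (adjusted p = 0.0110; adjusted p = 0.677 with an estimated correlation). Of 7 tested late granulocyte genes 0 changed by edgeR, over all genes and over the list alone, with 4 at an unadjusted p under 0.05 and 1 higher by limma-voom (adjusted p = 0.122 by camera). By DESeq2, which tested 16 members, 7 were higher, and by edgeR without knockdown replicate 3, where 9 were tested, 5. Among them were Lcn2 at 0.602 ± 0.535 and 7.39 ± 7.48 CPM and Csf3r at 1.57 ± 1.51 and 14.6 ± 12.9. Camera called it higher without scrambled replicate 3 (adjusted p = 0.0217) or knockdown replicate 3 (0.00354), and with the immediate early level as a covariate (0.0371, with 3 members that rose), over a range of 0.00354 to 0.364. Of the 8 fits that left out a library, Cst7 and Klf4 kept their calls in 1, that without knockdown replicate 3, with adjusted p of up to 0.0928, and Slc40a1 in all 8. With the early granulocyte level as a covariate, a fit added after seeing the data, 683 genes were called, 514 of them among the 2062, and 275 moved by over 1 log2 unit. The monocyte list then had an adjusted p of 0.734, over a range of 0.000967 to 0.734.

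**Figure D2:**
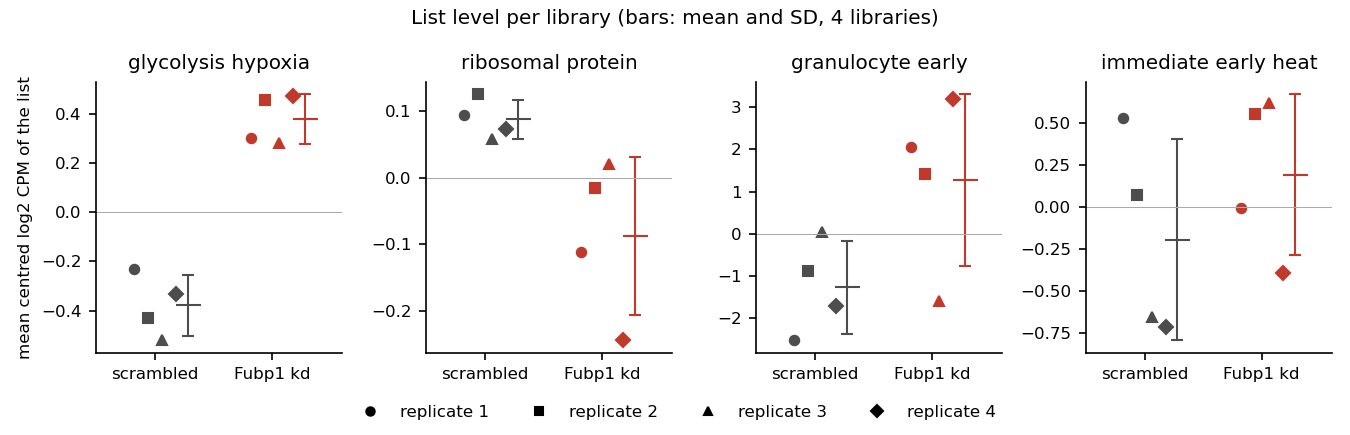
Level of 4 gene lists in each library, as the mean log2 CPM of the list's tested members centred gene by gene, with the mean and SD of the 4 libraries of each group. The glycolysis and hypoxia list separates the groups, while the early granulocyte list lies at -1.59 in knockdown replicate 3 and between 1.42 and 3.19 in the other 3 knockdown libraries.

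Genes of adhesion and homing moved in both directions. Of 14 tested members 4 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. The tetraspanin gene Cd9 rose from 3.05 ± 0.672 to 11.5 ± 3.07 CPM and Pecam1 from 4.51 ± 1.36 to 29.2 ± 14.9, as did Icam1 and Itga6 (log2 fold change 1.36), while the fibronectin receptor chain Itga5 fell from 152 ± 29.2 to 97.2 ± 9.57 (SD, n = 4 per group). The list was called higher by camera (adjusted p = 0.0387; adjusted p = 0.677 with an estimated correlation). The call ended without scrambled replicate 4 (adjusted p = 0.113) or knockdown replicate 4 (0.0808), with upper quartile factors (0.0544) and with library totals (0.0576), with limma-voom, and with the early granulocyte level as a covariate (0.208), over a range of 0.00277 to 0.208. Without knockdown replicate 3, 9 members rose. Cd9, Pecam1 and Icam1 kept their calls with each library left out, and Itga5 lost it without scrambled replicates 1, 2 or 3 or knockdown replicate 2, with an adjusted p of up to 0.0696.

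Few of the proliferation genes passed. Of 26 tested genes of DNA replication and the G1/S transition 3 fell and 0 rose, and 1 fell when adjusted over the list alone. They were the helicase genes Mcm2 (878 ± 51.4 to 719 ± 25.3 CPM) and Mcm7 (541 ± 24.4 to 454 ± 42.3), and Cdc6 (253 ± 8.77 to 197 ± 30.3; SD, n = 4 per group). Camera called the list lower (adjusted p = 0.00160; adjusted p = 0.677 with an estimated correlation). Of 28 growth genes driven by Myc 1 fell, Npm1 (log2 fold change -0.21), and 0 when adjusted over the list alone; the fitted change was below 0 in 24. Camera called them lower (adjusted p = 0.0138; adjusted p = 0.763 with an estimated correlation), which ended without scrambled replicate 4 (adjusted p = 0.123) or knockdown replicate 4 (0.259) and with limma-voom, over a range of 9.04e-05 to 0.427. Of 26 mitotic genes 2 fell, Birc5 (-0.40) and Cenpe (-0.26), and 1 when adjusted over the list alone, with no list call (adjusted p = 0.514) except without knockdown replicate 3 (adjusted p = 0.0153, in a range up to 0.959). With the early granulocyte level as a covariate the adjusted p was 0.590 for replication, 0.427 for Myc-driven and 0.119 for mitotic genes, the mitotic list then pointing up; for replication the range was 2.56e-06 to 0.590. Without knockdown replicate 3, 14 replication and 5 mitotic genes fell. Mcm2 lost its call without scrambled replicate 2 (adjusted p = 0.0523) and Birc5 without scrambled replicate 2 or knockdown replicate 1. Npm1, Mcm7, Cdc6 and Cenpe lost it without 4 to 7 of the 8 libraries in turn, with adjusted p of up to 0.108.

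In the p53 target list 3 of 21 tested genes fell and 1 rose, and 8 fell and 1 rose when adjusted over the list alone. The death receptor gene Fas fell from 1.21 ± 0.0841 to 0.412 ± 0.0662 CPM, Phlda3 from 36.8 ± 12.2 to 15.7 ± 5.60 (SD, n = 4 per group) and Plk2 by 1.39 on the log2 scale, while Pmaip1, which encodes the pro-apoptotic NOXA, rose (log2 fold change 0.95, adjusted p = 0.0498). The list was called lower by camera (adjusted p = 0.00785; adjusted p = 0.677 with an estimated correlation). With the early granulocyte level as a covariate its adjusted p was 0.204, and with limma-voom 0.0598, over a range of 0.000194 to 0.204. The number that fell was 7 without knockdown replicate 1, and 1 without scrambled replicates 1 or 2 or knockdown replicates 2 or 4. Of 20 apoptosis genes Pmaip1 and Birc3 (1.08), an inhibitor of apoptosis, rose and 0 fell, and 1 rose when adjusted over the list alone (adjusted p = 0.267 by camera). Of 12 tested genes reported elsewhere as FUBP1 targets Pmaip1 alone passed, and 0 when adjusted over the list alone (adjusted p = 0.744 by camera), with a median below 0 and a test pointing down but a mean above 0. Among them were 3 named after their values were seen: Myc at 228 ± 26.7 and 174 ± 67.4 CPM (adjusted p = 0.350), Cdkn1a at 136 ± 51.7 and 103 ± 33.9 (0.391) and Kit at 143 ± 70.4 and 78.7 ± 27.5 (0.158). Fas kept its call with each library left out; Plk2, Phlda3, Pmaip1 and Birc3 lost it without 4 to 7 of the 8 libraries in turn, with adjusted p of up to 0.122.

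Stem and progenitor genes did not move together. Of 25 tested members Lmo2 and Mllt3 (152 ± 17.3 to 98.0 ± 9.67 CPM; SD, n = 4 per group, adjusted p = 0.00880) fell and 0 rose by edgeR, with 5 higher at an unadjusted p under 0.05 and the same 2 when adjusted over the list alone. Without knockdown replicate 3, where 26 were tested, 5 rose, and with all libraries DESeq2 called 3 higher and limma-voom 1. Camera did not call the list (adjusted p = 0.652); its median, mean and camera pointed up and fry down, and camera too pointed down without scrambled replicate 4. With the early granulocyte level as a covariate camera called it lower (adjusted p = 0.0129, in a range up to 0.983). Of 15 targets of the MAPK pathway the phosphatase genes Dusp5 (log2 fold change 1.75) and Dusp4 (1.47) rose, and the Spry4 gene, an inhibitor of the pathway, and Etv5 fell by 1.31 and 0.76; the numbers were the same when adjusted over the list alone (adjusted p = 0.540 by camera). These 4 lost the call without 4 to 6 of the 8 libraries in turn, with adjusted p of up to 0.0841. Of 24 DNA repair genes 0 changed by edgeR over all genes or over the list alone, with 7 at an unadjusted p under 0.05, 4 lower by DESeq2 and 6 lower by limma-voom (adjusted p = 0.0999 by camera), and with Parp1 at 609 ± 26.9 and 620 ± 23.4 CPM. Without scrambled replicate 4, knockdown replicate 3 or knockdown replicate 4, 2, 3 and 1 fell. Camera called the list lower without scrambled replicate 1 (adjusted p = 0.0369) or knockdown replicate 3 (0.0116), with limma-voom and with no low count filter (0.00444), in a range up to 0.444. Of 25 interferon genes Ifit2 rose (0.31, adjusted p = 0.0483), a call lost whichever library was left out, and 0 when adjusted over the list alone (adjusted p = 0.638 by camera). Its median and mean lay below 0 and its test pointed up; the median lay above 0 without scrambled replicate 3 or knockdown replicate 2, and the test pointed down without scrambled replicate 4 or knockdown replicate 1. Camera called it higher without scrambled replicate 3 (adjusted p = 0.0206, in a range up to 0.930).

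Markers of other cells and signs of handling were mostly at low levels or did not pass. No gene passed among 10 tested of mast cells, basophils and eosinophils (adjusted p = 0.443 by camera, 0.0479 without knockdown replicate 3, in a range up to 0.983) or 5 of stroma and endothelium (0.330), over all genes or over the list alone. Of 4 B cell genes 0 passed over all genes and 1 over the list alone (adjusted p = 0.715, and 0.0127 with no low count filter, in a range up to 0.930). Xbp1 rose among 5 plasma cell genes, of which 2 rose and 2 fell when adjusted over the list alone (adjusted p = 0.749, with a median above 0 and a mean below it). The T and NK cell list had 2 tested members and no list test, except with no low count filter, where camera called it higher (adjusted p = 0.00850). They were Lck (1.97 ± 0.611 and 5.36 ± 4.55 CPM, SD, n = 4 per group) and Gzmb (2.63 ± 1.43 and 8.33 ± 7.86), and both passed over the list alone and neither over all genes. No gene passed, over all genes or over the list alone, among 16 immediate early and heat shock genes (adjusted p = 0.176, 0.0320 without scrambled replicate 1 and 0.0149 without knockdown replicate 4, in a range from 3.51e-05 with the early granulocyte covariate to 0.585), 26 histone genes (0.213) or 7 mitochondrial genes (0.122, and 0.00888 without knockdown replicate 1, in a range up to 0.654). At an unadjusted p under 0.05 these edgeR tests gave 1 mast cell, 1 stromal, 1 B cell, 4 immediate early, 1 histone and 3 mitochondrial genes; DESeq2, run without the low count filter and so on more members of some lists, called 2, 1, 2, 0, 0 and 2 higher, and limma-voom 1 mast cell gene and 0 in the others. By edgeR 2 mast cell genes and 1 each of the B cell, stromal, immediate early and histone lists rose without knockdown replicate 3, and 2 mitochondrial genes without knockdown replicate 1. In all, camera called 14 of 30 lists, 9 higher and 5 lower, of which none held with an estimated correlation (smallest adjusted p = 0.590). Fry called 7, the FUBP family, STAT5, NF-kB, unfolded protein, glycolysis, megakaryocyte and ribosomal protein lists.

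**Figure D3:**
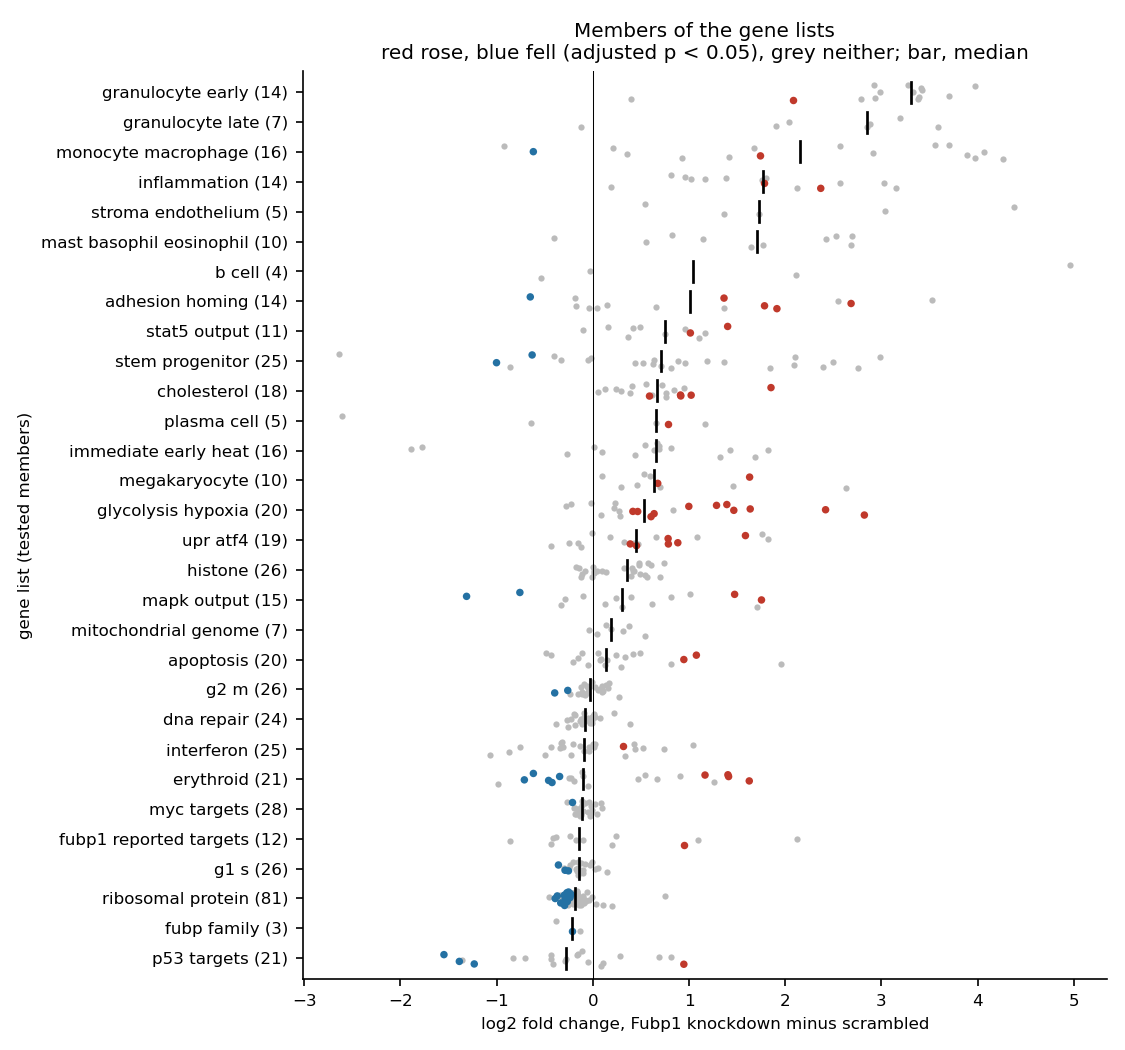
Fitted log2 fold change, knockdown minus scrambled, of each tested member of the 30 gene lists with at least 3 tested members, in colour where the gene passed an adjusted p of 0.05, with the list's median as a bar. In the glycolysis and hypoxia list 11 of 20 members rose, and in the ribosomal protein list 16 of 81 fell.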

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

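The tests over other splits of the libraries for the 2 counts of genes were chosen only after the result was seen; that for the number of lists was chosen before. The 8 libraries can be split into 4 and 4 in 35 ways. Of these, 1 called as many as 2062 genes, the real split, and the highest count of any other split was 1. Likewise 1 of the 35 splits, the real one, gave as many as 692 genes over 1 log2 unit, and the highest of the others gave 0. Chance assignment of these libraries is thus excluded at 1 in 35 for both counts. A difference in processing that runs with the groups would give the same result. The labels do not say which library had which depletion kit, so this could not be tested. Chance assignment is not excluded for the number of gene lists called by camera with its preset correlation: 8 of the 35 splits called as many as 14 lists. Splits other than the real one called from 4 to 17 lists. Over the 14 called lists, the splits with a camera p as small ran from 3 of 35 for glycolysis to 20 of 35 for Myc-driven genes, the real split included.

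In 216 groups of 4 values, those of the named genes and of the measures per library, 16 held a library far from the other 3, where chance flags about 1 in 20 groups, or 10.8. Fubp1 was 396 CPM in scrambled replicate 4 against 284 to 296 in the other scrambled libraries. Pimreg was 0.450 CPM in the same library against 1.69 to 1.89, Spry4 15.2 CPM against 18.9 to 19.7, and Herpud1 60.9 CPM against 72.2 to 73.2. Scrambled replicate 3 was low in Mcm2, at 801 CPM against 901 to 906, and high in Lcn2, at 1.40 CPM against at most 0.369. Sparc, a matrix protein gene, was 2.92 CPM in scrambled replicate 2 against at most 0.208 in the others. Knockdown replicate 1 was high in 4 genes: Sparc at 69.5 CPM against at most 0.718, the collagen gene Col1a2 at 397 against at most 41.3, Gzmb at 20.1 against at most 5.09, and Phlda3 at 24.0 against at most 13.9. Knockdown replicate 3 was high in Chrm4, at 7.43 CPM against at most 4.23, Rcbtb1, at 32.6 against 30.9 to 31.1, and Blm, at 214 against 173 to 177. Knockdown replicate 4 was low in Ptpn13, at 1.33 CPM against 4.00 to 4.32, and high in Lck, at 12.2 against at most 3.57.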

How the results depend on the processing

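The fits with the early granulocyte or the immediate early level as a covariate were chosen only after the data were seen. All 2062 calls kept their sign wherever they were called in another fit, and 36 of the 80 called named genes passed with each library left out. The number of calls moved by more than 1.5 times under several settings. DESeq2 called 2035 genes higher, 1553 lower and 1350 over 1 log2 unit, and limma-voom with quality weights 1861, 1887 and 1044; each also called 2044 of the 2062. On simulated libraries DESeq2 made 55 false calls over 25132 genes, against 9 by edgeR over 13643. GlmTreat against a fold change of 1.2, a stricter test by construction, called 459 genes. With the early granulocyte covariate 458 were higher, 225 lower and 275 over 1 log2 unit, and with the immediate early covariate 1150 passed 1 log2 unit. Of the 80 called named genes 38 lost the call with the early granulocyte covariate. The lists called numbered 9 with the early granulocyte covariate, 0 with an estimated correlation and 7 with fry. With single libraries left out, genes higher ran from 275 (without scrambled replicate 2) to 1956 (without knockdown replicate 3), genes lower from 251 to 1469 and genes over 1 log2 unit from 220 to 1495 in the same fits. The 2042 calls shared with the authors' deposited table became 3406 when DESeq2 was run here. Fubp1 passed with no low count filter (log2 fold change -0.41) and with DESeq2 (-0.39). It was at -0.25 with limma-voom and at -0.28 without scrambled replicate 4, and passed in neither. Apart from fewer samples and the stricter test, the cause was not tested.

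The replicate numbers did not pair the libraries. Correlations were taken on what was left of log2 CPM after each gene's group mean was removed. They were -0.42, 0.02, -0.56 and -0.22 for same-numbered libraries, and no scrambled library correlated best with its own number. With the replicate block 195 genes were higher, 205 lower and 182 over 1 log2 unit; it takes up degrees of freedom by construction. The 14 called lists kept their camera call with it. EdgeR called 0 ribosomal protein, 0 cholesterol and 0 replication genes, with 31, 7 and 4 at an unadjusted p under 0.05, and 3 glycolysis genes. Of the 80 called named genes 43 lost the call.

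For the 99 named genes other than Fubp1, 1510 of 1861 values under alternatives kept direction and side of the threshold, 306 kept direction and lost the call, 15 gained it, 2 with no test moved and 28 reversed. Of the 99 genes 80 were called in the main fit, so values that kept their side include those of genes without a call. The reversals concern 10 genes, none called, and the cause was not tested. With the early granulocyte covariate Csf3r was at -0.18, Hdc -0.44, Sparc -0.58, Cd24a 0.14 and mt-Co1 0.025. With the immediate early covariate Blm was at -0.0081, Hist1h1c -0.25 and mt-Cytb -0.0077. With limma-voom Hist1h1c was at -0.088 and mt-Cytb at -0.081, with no low count filter Blm at -0.014 and Hist1h1c at -0.0079, and with library totals Cd24a at 0.0022. With single libraries left out the log2 fold change ran from -0.0077 to 0.047 for Parp1, -0.079 to 0.048 for Blm, -0.12 to 0.040 for Cd24a, -0.64 to 1.74 for Col1a2, -1.08 to 6.85 for Sparc, -0.15 to 0.15 for Hist1h1c, -0.12 to 0.021 for mt-Co1 and -0.072 to 0.11 for mt-Cytb. At these depths and with 4 libraries a group, 30 of 67 simulated 1.5-fold changes were called, so changes of that size can be missed. Only 200 genes were changed there, against 2062 called in the data, so the adjusted threshold was stricter in the simulation. The share missed in the data was thus not measured. Depth alone was not varied.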

Other observations

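The tests of the myeloid genes and, for the 3′ UTR word, those of other splits, base composition and guide pairing were chosen only after the result was seen, and both covariate fits were added after seeing the data. Some genes outside the rule, named after their values were seen, add to the account. Hif3a, which encodes a hypoxia-inducible factor subunit that can dampen the response, fell from 114 ± 18.1 to 41.1 ± 6.16 CPM (SD, n = 4 per group; log2 fold change -1.47, SE 0.14, adjusted p = 0.00192 by edgeR). Spi1, the gene of the myeloid transcription factor PU.1, rose by 2.54 (adjusted p = 0.0490), and measured 26.7, 18.6, 3.27 and 54.9 CPM in knockdown replicates 1 to 4. The transferrin receptor gene Tfrc (2130 ± 203 and 1973 ± 279 CPM, adjusted p = 0.516) and the proliferation marker gene Mki67 (2239 ± 196 and 2360 ± 384 CPM, adjusted p = 0.687) did not pass.

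Myeloid genes were high in knockdown replicates 1, 2 and 4. Of 37 tested members of the early granulocyte, late granulocyte and monocyte lists, 31 were lowest in replicate 3 among the knockdown libraries, and in 26 the other 3 knockdown libraries lay above all scrambled ones. These counts restate the pattern and do not test its cause. Mpo, its most abundant gene named here, reached 2169 CPM, and the lineage gate would remove mature cells but not early granulocyte progenitors. Since 3 of the 4 knockdown libraries and not all 4 lay above the scrambled range, a different share of myeloid cells in each library, an effect of the knockdown in every mouse and a difference between mice cannot be told apart with 4 mice a group.

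The rise of glycolysis genes was also tested. Had the myeloid share set it, the list's median of 0.54 should fall by most of its size with the early granulocyte covariate; it was 0.65 and camera still called the list higher. This argues against the myeloid share as the whole cause. With the immediate early level as a covariate the median was 0.48 and the list was still called. That level was taken as a sign of stress between death and lysis, which was not tested. It did not separate the groups (exact permutation p = 0.314), so this fit had little room to change the median and does not decide on stress. What stays open is such stress, and chance, since in 3 of the 35 splits, the real one included, the list's camera p was as small. An effect of the shRNA other than through Fubp1 was not tested for these genes either, so a biological cause remains a hypothesis.

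A scan of 15627 words of 7 bases in the 3′ UTRs of 11419 tested genes gave another pattern. The word with the lowest score was AAAGGTC, found in 1095 of them, with t = -8.27 and a shift of -0.27 SD toward lower expression in the knockdown. The next lowest word sharing no 6 bases with it had t = -5.28, and the largest score upward was 4.90. The word was in 164 of 939 genes that fell (17.5%), 95 of 1027 that rose (9.25%) and 836 of 9453 others (8.84%). The odds ratio for genes that fell was 2.18 (Fisher's exact p = 4.98e-15, across genes, which are not independent). The word was picked as the lowest of 15627 on these same genes, and this p does not allow for that choice. The odds ratio therefore restates the scan and is not separate support. The median log2 fold change was -0.05 with 1 site and -0.08 with more, against 0.0003 without, so the shift per gene was small. Among the 5 genes that fell with the smallest p, Lmo2, Rcbtb1 and Extl3 hold 1 site each, and Nxpe4 and Klhl23 hold 0. Of the named genes with the largest decreases, Gpx3 holds 1 site and Chrm4 was not searched. The others, Ptpn13, Tcf23, Oxtr, Trim2, Ugt8a, Vsig10, Fam198b and Sphk1, hold 0. Some named genes that rose also hold the word: Tpm4 and Cxcl2 with 1 site each, and Il6st with 2. The other called named genes that rose hold 0.

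For that word, 1 of the 35 splits, the real one, gave a t as large in size (8.27). The highest of the others was 7.30, for another word; this word's own highest was 6.94, and 3.93 in the 18 splits with 2 libraries of each group on each side. So chance assignment of the libraries is excluded at that share. The myeloid share is argued against as the whole cause: with the early granulocyte covariate the word's t was -9.03, still the lowest. Among 411 other words of the same bases the lowest t was -6.22, that of AAGGTCA, which overlaps the word itself. The word was picked as the lowest of all, so none of these could have been lower. That comparison therefore does not decide on base composition beyond the length and GC content in the fit. A candidate explanation is that the guide strand of the Fubp1 shRNA pairs through its seed with other mRNAs. The word's t was -2.28 in coding sequences, and its reverse complement GACCTTT had -0.50 in 3′ UTRs. These 2 values do not favour the guide over a binding protein or microRNA, and the word was picked for its low t in 3′ UTRs. It occurs once in the Fubp1 coding sequence, at base 422 of 1962, in exon 7 of 20 (chromosome 3 from 152218231 to 152218237 on the plus strand, GRCm38). Occurrence in Fubp1 alone is weak evidence, since 9.17% of 2378 coding sequences of like length hold the word, and the shRNA sequence is not given in the sources used here. If it holds, part of the genes that fell, Lmo2 possibly among them, could follow from the shRNA and not from less FUBP1; a binding protein or microRNA with the same site was not tested.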
